A study of Mus musculus with 10 samples.

How the data were processed

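Islets were isolated by collagenase perfusion of the pancreas from male NZO/Hl and C3HeB/FeJ mice at 6 weeks of age, per the labels' protocols. The mice had received a diet with 45% of its energy from fat since weaning at day 21, and the islets were kept overnight in culture medium with 10 mM glucose before RNA extraction, per the labels' protocols. RNA with an integrity number above 8 was used, and 150 ng of total RNA per array was amplified, labelled with biotin and measured on a whole-transcript Affymetrix mouse gene array, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA in the Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays together and summarises the probes of a probe set, so the values carry no detection call, compress differences of dim and very bright probe sets, and force a similar distribution on every array. The software version, probe set library and genome build are not given in the sources used here. No further normalization was applied.

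The table holds 35556 probe sets on 10 arrays. A probe annotation gave exactly 1 gene symbol for 21789 probe sets and several for 1621, and 12146 are not named here. Of the single-symbol probe sets, 21698 were matched by Entrez ID to a gene table of the assembly GRCm38.p6, which changed no symbol and gave the chromosome and the order of the genes. One row per gene was kept, the probe set with the highest mean over all arrays where a gene had several (999 genes), which left 19938 genes, with no filter on dim genes. Groups were the 2 strains, 5 arrays each. Replicate numbers follow the order of deposition and pair nothing. Most titles carry 2 animal numbers, that of NZO replicate 4 carries 1 and that of NZO replicate 5 a range, and the labels do not say whether arrays are pools of separate animals, so p-values measure the spread between these samples. The labels give no batch.

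Differences are NZO minus C3H from lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. An SE is that of the limma difference, and a mean ± SD is over the 5 arrays of a strain on the log2 scale. The script was tested on simulated data with the real means and spreads of the 19938 genes, of which 200 were changed. It recovered 68% of genes changed by 0.5 log2 units, 96% of those changed by 1 and 100% of those changed by 2 or 3, with 9 false calls. The simulation drew the noise of each gene independently and so lacked variation that genes share on an array. These figures are therefore not error rates of the real comparison. The region was the set of genes that start between 30 and 46 Mb of chromosome 7 in GRCm38.p6, of which 255 were tested, where the gene table holds 331 protein-coding genes, and was compared with the rest of the genome by Fisher's exact test.

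The 30 gene lists, 453 measured genes of 508, covered beta cell identity, insulin granules and exocytosis, stimulus-secretion coupling, alpha, delta and PP cells, acinar, duct, endothelial, macrophage, lymphocyte, stellate and Schwann cells, antigen presentation, interferon response, inflammation, endoplasmic reticulum stress, oxidative stress, cell cycle, glycolysis, oxidative phosphorylation, genes disallowed in beta cells, beta cell stress, cholesterol synthesis, lipogenesis, fatty acid oxidation, hypoxia, immediate early genes, the Reg family, ribosomal proteins and genes from earlier NZO crosses. They were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, which called 17 lists, 12 higher and 5 lower in NZO. Beside it stand camera with an estimated correlation, which called 1, and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes and called 12. At the preset correlation, 14 of 100 splits of the 10 arrays into 5 and 5, the real one included, gave as many lists as the strains. Adjusted p values of camera at that setting are therefore not error rates.

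The genes named in the text follow a rule fixed before the data were examined, as were the report's limma, Fisher and gene list tests, the gene lists and most alternatives. Some tests under the additional observations were chosen later, as stated there. The rule names the 12 largest positive and the 12 largest negative differences among called genes whose strains do not overlap, without predicted, clone-named, olfactory, vomeronasal and small RNA genes, and the 10 region genes with the smallest p. It also names Atp4a, Pop4, Abcc8 and Kcnj11, up to 4 called members of each list with the smallest p, and the islet hormones. Members of a list named beyond these stand for their values only.

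Alternatives chosen with them were a filter on dim genes at the median and at the 25th percentile of brightness, a second quantile normalization, centring of each array on its median, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, all probe sets as rows, a size threshold of 1 log2 unit, region borders moved by 1 Mb, the other set tests, and leaving out each array in turn. The acinar score as a covariate and the joint omission of NZO replicates 4 and 5 were chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9.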

Results

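Gene expression was measured in pancreatic islets, the hormone-secreting cell clusters of the pancreas, of 2 inbred mouse strains. NZO mice are obese and prone to diabetes, and C3H mice (C3HeB/FeJ) served as the other strain in crosses with them. There were 10 arrays, 5 per strain, all from male mice aged 6 weeks that had received a high-fat diet since weaning. The array medians over all probe sets lay between 6.93 and 7.05 on the log2 scale, and arrays of one strain correlated at 0.983 to 0.997 over all genes tested. The mean log2 value of 24 pancreatic acinar genes, called the acinar score here, was 8.04 to 8.88 on the C3H arrays, 9.76 to 10.4 on NZO replicates 1 to 3, and 11.7 and 11.6 on NZO replicates 4 and 5. These last 2 arrays are also the ones whose titles do not carry 2 animal numbers. The labels do not say whether their samples were made up differently. C3H replicate 4 stood apart from the other C3H arrays, with the highest median of all arrays (7.05) and a value of 33.9 on the second principal component, where the other C3H arrays lay between -15.1 and 0.342.

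The first comparison asked which islet transcripts differed between the strains. Transcripts of pancreatic digestive enzymes and of the Reg family, small secreted lectins named for islet regeneration, were far higher in NZO islets, while Rab3c, Tac1 and Nefm were among the genes that were far lower. Prss3, a trypsinogen, was 5.72 log2 units higher (SE 0.62, limma adjusted p = 3.52e-05), at 5.09 ± 0.22 in C3H and 10.81 ± 1.82 in NZO (SD, n = 5 each). Its C3H level lay below the 25th percentile of every array (5.65 to 5.85) and was not shown to be above background, so no fold is given for it or for other genes with a strain mean that low. Reg3b was 4.57 higher (SE 0.39, 23.8-fold) and Cldn11, which encodes a tight junction claudin, 3.58 higher (SE 0.11, 11.9-fold). Rab3c, which encodes a small GTPase of secretory vesicles, was lower by 7.15-fold (log2 difference -2.84, SE 0.09, limma adjusted p = 1.01e-10), at 9.38 ± 0.03 in C3H and 6.54 ± 0.19 in NZO. The tachykinin precursor Tac1 differed by -2.03 (SE 0.26) and the neurofilament gene Nefm by -2.19 (SE 0.16).

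Of 19938 genes tested with limma, 2010 differed at a Benjamini-Hochberg adjusted p below 0.05, 1090 higher and 920 lower in NZO, and 232 of them by at least 1 log2 unit (162 higher, 70 lower). The values of the 2 strains did not overlap in 1822 genes, or 9.14%, where chance gives 0.794%. The other genes among the 12 largest positive differences were the trypsinogens Try4 (3.94), Try5 (3.44) and Try10 (3.03), the trypsin inhibitor Spink1 (3.34), the mucosal glycoprotein gene Dmbt1 (3.13), Reg1 (2.89), Reg2 (2.84), the kallikrein Klk1b5 (2.87) and the pancreatic phospholipase Pla2g1b (2.64). The other genes among the 12 largest negative differences were Klk1b22 (-3.00), the aldo-keto reductase Akr1c12 (-2.79), Zfp979 (-2.26), Pianp (-2.25), the carbohydrate kinase Fggy (-2.08, but -0.38 in its other probe set), the calcium-binding protein gene Calb1 (-1.76), Rnf7 (-1.73), the transporter Slc6a17 (-1.71) and Ndst4 (-1.64). The trypsinogens, the kallikreins of the Klk1b group and the aldo-keto reductases are families of near-identical copies, so the identity of the copy that each probe set measured is uncertain. When the acinar score was added as a covariate beside strain, 206 genes passed, 187 of them among the 2010. Because the score differed between the strains, this covariate multiplied the SE of a strain difference by a factor of 2.12 before any change in the residual spread. Of the 1823 genes that no longer passed, 761 kept their sign and at least 0.75 of their size, and 264 turned to the opposite sign. Without NZO replicates 4 and 5, 1105 genes passed, 1051 of them among the 2010. Cldn11 (3.43), Rab3c (-2.84), Pianp (-2.15), Klk1b22 (-3.13), Reg3b (2.01), Reg1 (0.75) and each of the 12 largest negative differences except Calb1, which kept over 0.75 of its size but at an SE of 0.42 against 0.20, were among the 187. The values of Spink1 (-0.53), Dmbt1 (-0.03) and Try10 (-0.15) turned negative without passing. Leaving out C3H replicate 4 raised the number of genes lower in NZO from 920 to 1574.

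Acinar transcripts formed the largest difference among the gene groups. Of the 24 measured acinar genes, 22 were higher in NZO, over all genes and adjusted over the list alone, with a median log2 difference of 2.22. The chymotrypsinogen Ctrb1 rose from 11.14 ± 0.52 to 13.26 ± 0.54, and the ribonuclease Rnase1 from 8.34 ± 0.42 to 10.67 ± 0.75. The transcription factor genes Bhlha15 (-0.18, SE 0.10) and Ptf1a (0.18, SE 0.12) did not pass. The camera test of limma called the list higher at an adjusted p of 2.69e-25, but not with an estimated correlation (adjusted p = 0.185). Of the 7 Reg family genes, 6 were higher, also adjusted over the list alone, with a median of 1.82. Reg3b reached 10.86 ± 1.06 in NZO against 6.29 ± 0.44 in C3H, Reg3g differed by 1.82 (SE 0.28) and Reg3d by 1.63 (SE 0.25), whereas Reg4 differed by -0.05. The Reg list was called at an adjusted p of 7.86e-09 by camera of limma, with an adjusted p = 0.185 with an estimated correlation. Within NZO the Reg mean was highest where the acinar score was highest, at 9.24 and 8.74 on NZO replicates 4 and 5 against 7.53 to 8.21 on the others. The median of the Reg list was 0.16 with the acinar score as a covariate, where Reg3b and Reg1 passed.

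**Figure D1:**
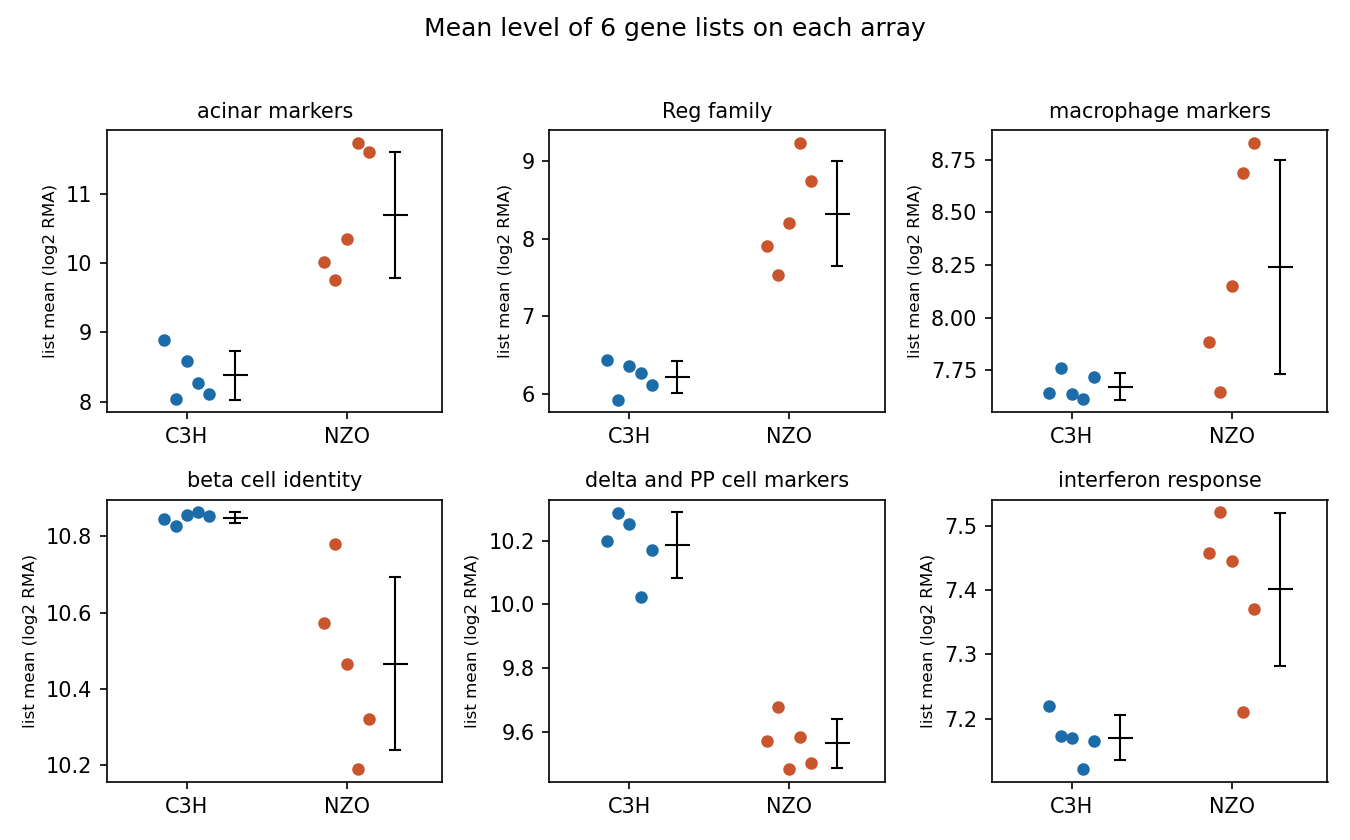
Mean log2 RMA value of 6 gene lists (y axes, each panel with its own range) on each of the 5 C3H and 5 NZO arrays (points), with the mean and SD of each strain (black bars). The acinar score of each NZO array (9.76 to 11.7) lies above that of each C3H array (8.04 to 8.88), and the delta and PP cell means of NZO (9.48 to 9.68) lie below those of C3H (10.0 to 10.3).

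Markers of the islet's delta and PP cells were lower in NZO. Of 8 measured genes, 6 were lower over all genes and 7 adjusted over the list alone, with a median of -0.50. Somatostatin (Sst) was 13.87 ± 0.04 in C3H and 13.12 ± 0.26 in NZO, a 1.68-fold difference (log2 difference -0.75, SE 0.11, limma adjusted p = 0.000379). Its C3H level lay close to the highest value of any array (13.96 to 14.05), where differences are compressed, so that fold may be too small. Rbp4, which encodes the retinol carrier of the blood, was 2.45-fold lower (-1.29, SE 0.11), Ptprz1 2.05-fold lower (-1.03, SE 0.21) and pancreatic polypeptide (Ppy) 1.33-fold lower (-0.41, SE 0.08). This list passed camera of limma at an adjusted p of 8.34e-08 with the preset correlation and was the only list of 30 past the threshold with an estimated correlation (adjusted p = 0.0181). Its median was -0.53 to -0.40 under all 21 alternatives, the acinar score as a covariate included, although only 1 member, Spock3, then passed on its own.

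Several genes that mark the insulin-secreting beta cell were lower in NZO, but not the insulin gene that was measured. Of 19 measured beta cell identity genes, 6 were lower and none higher, 10 lower adjusted over the list alone, with a median of -0.23. The glucose transporter Slc2a2 was 2.92-fold lower (-1.54, SE 0.29, limma adjusted p = 0.00309), the secreted peptide gene Ucn3 2.18-fold (-1.12, SE 0.19), the granule zinc transporter Slc30a8 2.14-fold (-1.10, SE 0.16) and the transcription factor gene Isl1 1.73-fold (-0.79, SE 0.09). Ins2 was 12.33 ± 0.07 in C3H and 12.45 ± 0.15 in NZO, a difference of 0.12 (SE 0.08, limma adjusted p = 0.477), and Nkx6-1 differed by 0.01 (SE 0.14). The Ins2 probe set was bright, and RMA compresses differences of very bright probe sets, so its difference may be understated. Ins1 was not analysed here, because no probe set carried its name alone. The list was called lower by camera of limma at an adjusted p of 4.54e-05, with an adjusted p = 0.391 with an estimated correlation. The beta cell mean was lowest where the acinar score was highest, at 10.19 and 10.32 on NZO replicates 4 and 5 against 10.47 to 10.78 on the other NZO arrays and 10.83 to 10.86 in C3H. No member passed with the acinar score as a covariate, where the median of the list was 0.09. Of the 6, Slc2a2 (0.07, SE 0.38), Ucn3 (-0.09, SE 0.25) and Slc30a8 (-0.18, SE 0.19) were then near 0, Isl1 (-0.50, SE 0.18) and Pax6 (-0.21, SE 0.17) were smaller, and Npy went from -0.59 (SE 0.13) to -0.77 (SE 0.28). All 6 members passed with those 2 arrays left out.

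Of 20 insulin granule and exocytosis genes, 3 were lower, among them Rab3a (-0.53, SE 0.10) and Sytl4 (-0.59, SE 0.13), and 5 lower and 2 higher adjusted over the list alone. The list, with a median of -0.11, was called lower by camera of limma at an adjusted p of 0.0436, with an adjusted p = 0.391 with an estimated correlation. Leaving out C3H replicate 3 (limma camera adjusted p = 0.110), C3H replicate 5 (0.0670) or NZO replicate 4 (0.143) each ended that call, as did centring, both brightness filters and fry (adjusted p = 0.0686). Of 18 stimulus-secretion genes, pyruvate carboxylase Pcx (-0.59, SE 0.13) and the incretin receptor Gipr (-0.44, SE 0.10) were lower and the calcium channel Cacna1c higher (0.32, SE 0.09). The list, with 4 lower and 3 higher adjusted over the list alone, was not called by limma's camera (median -0.13, adjusted p = 0.322). The call of Cacna1c ended without C3H replicate 1, 2 or 4 or NZO replicate 1, 3 or 5 (limma adjusted p up to 0.0980). Of 7 alpha cell genes, 3 were lower, the same number adjusted over the list alone, among them the amino acid transporter Slc7a2 (-0.57, SE 0.12). Glucagon (Gcg) was 13.25 ± 0.06 and 13.21 ± 0.12, a difference of -0.04 (SE 0.08, limma adjusted p = 0.828). At this brightness RMA compresses differences, so one in Gcg could be understated. The alpha cell list, with a median of -0.23, had a camera adjusted p of 0.00641 in limma, with an adjusted p = 0.185 with an estimated correlation. Its call also ended above median brightness. The medians of the granule (0.08) and stimulus (0.15) lists turned positive with the acinar score as a covariate, and that of the alpha list was -0.11.

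Markers of cell types other than endocrine cells were higher in NZO in several lists, and each of these lists lost its call with an estimated correlation. Of 16 macrophage genes, 6 were higher and 1, Cx3cr1 (-0.28), lower, and 12 were higher and 1 lower adjusted over the list alone. Camera of limma called the list, whose median was 0.67 (adjusted p = 1.83e-06), but not with an estimated correlation (adjusted p = 0.391). Fry did not call it either (adjusted p = 0.0746). The macrophage mean was 8.685 and 8.83 on NZO replicates 4 and 5, against 7.65 to 8.15 on the other NZO arrays and 7.61 to 7.76 in C3H. Without those 2 arrays the list kept its camera call, but only 2 of its genes passed. Csf1r, the receptor of a macrophage growth factor, was 1.69-fold higher (SE 0.17 on the log2 scale) and Fcer1g 1.59-fold higher (SE 0.14). Of 16 stellate cell and fibroblast genes, 3 were higher, 7 adjusted over the list alone, among them Pdgfra (1.25, SE 0.25). With a median of 0.38, the list was called by camera of limma (adjusted p = 0.000111), but not with an estimated correlation (adjusted p = 0.391). The stellate call also ended with fry (adjusted p = 0.146) and without NZO replicates 4 and 5. Of 10 duct genes, 3 were higher, 5 adjusted over the list alone, among them the keratin Krt19 (1.55, SE 0.24) and the mucin Muc1 (1.58, SE 0.28). The list median was 0.32 and camera of limma called it (adjusted p = 0.00641), but not with an estimated correlation (adjusted p = 0.391). The duct list was also no longer called without C3H replicate 4 (limma camera adjusted p = 0.0974), above median brightness or with fry (adjusted p = 0.0686). Of 14 endothelial genes, 3 were higher, the same number adjusted over the list alone, among them Emcn (0.51, SE 0.08). Camera of limma called the list, whose median was 0.22 (adjusted p = 0.000146), but not with an estimated correlation (adjusted p = 0.391). Under the acinar covariate the medians were -0.49 for macrophage, -0.45 for stellate and -0.20 for duct genes and 0.14 for endothelial genes. None of the 12 lymphocyte genes passed (median -0.01, mean -0.01, camera of limma in the opposite direction with adjusted p = 0.997). Of 6 Schwann cell genes Ngfr was lower (-0.57, SE 0.11), also adjusted over the list alone, with a list median of -0.11 (camera of limma, adjusted p = 0.269).

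Some interferon-induced genes and some genes of antigen presentation were higher in NZO, and neither list was called with an estimated correlation. Of 18 interferon response genes, 5 were higher and 1 lower, 6 higher and 1 lower adjusted over the list alone. With a median of 0.16, the list was called by camera of limma (adjusted p = 0.00119), but not with an estimated correlation (adjusted p = 0.269). The antiviral GTPase gene Mx1 was 3.01-fold higher (1.59, SE 0.30), Oasl2 0.68 higher (SE 0.08) and the RNA sensor Ifih1 1.56-fold (0.64, SE 0.08), and Mx2 was lower (-0.59, SE 0.09). Mx1 (3.33), Ifih1 (0.77) and Rsad2 (0.95) also passed with the acinar score as a covariate. Of 12 genes of the major histocompatibility complex and its loading machinery, 3 were higher, 4 adjusted over the list alone, among them Psmb8 (0.50, SE 0.10) and B2m (0.41, SE 0.10). The list median was 0.14 and camera of limma called it (adjusted p = 0.00641), but not with an estimated correlation (adjusted p = 0.391). Fry did not call it either (adjusted p = 0.0686). Of 19 inflammation genes, Il6 (2.83-fold), Ptgs2 (1.17, SE 0.28) and Lcn2 (0.86, SE 0.25) were higher, 4 adjusted over the list alone. Camera of limma called the list, whose median was 0.16 (adjusted p = 0.0028), but not with an estimated correlation (adjusted p = 0.391). The inflammation call also ended with fry (adjusted p = 0.138) and without NZO replicates 4 and 5, where Ptgs2 and Lcn2 lost their calls too. Lcn2 lost its call when any array except NZO replicate 2 was left out (limma adjusted p up to 0.113). The medians of the antigen presentation (-0.07) and inflammation (-0.21) lists turned negative with the acinar score as a covariate.

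Some genes of proliferation and some that mature beta cells keep low were higher in NZO, but most members of both lists did not pass. Of 25 cell cycle genes, 6 were higher, among them Mki67 (0.44, SE 0.11), Top2a (0.46, SE 0.11) and the mitotic kinase Plk1 (0.39, SE 0.08), and the D-type cyclins Ccnd1 (-0.24, SE 0.06) and Ccnd2 (-0.40, SE 0.08) were lower. Adjusted over the list alone, 10 were higher and 2 lower. With a median of 0.20, the list was called by camera of limma (adjusted p = 0.000172), but not with an estimated correlation (adjusted p = 0.303). None of these genes passed with NZO replicates 4 and 5 left out, where Plk1 was 0.35, Mki67 0.40 and Top2a 0.33 and the list kept its camera call in limma (median 0.13, adjusted p = 0.0109). None passed with the acinar score as a covariate either, where Plk1 was 0.25, Mki67 0.25 and Top2a 0.18, and the list median was -0.01. Of 19 genes described as disallowed in beta cells, 6 were higher, 9 adjusted over the list alone, among them the small GTPase regulator Arhgdib (0.64, SE 0.10) and Tgm2 (1.12, SE 0.22). The list median was 0.32 and camera of limma called it (adjusted p = 2.9e-06), but not with an estimated correlation (adjusted p = 0.391). Fry did not call the disallowed list (adjusted p = 0.0686). Its mean was 8.36 and 8.28 on NZO replicates 4 and 5, against 7.57 to 7.99 on the other NZO arrays. One of the 6, Pdgfra, is also on the stellate cell list. Of 10 genes linked to beta cell stress and loss of identity, Aldh1a3 was 1.68 higher (SE 0.12, limma adjusted p = 6.42e-07) and Cck 2.46-fold higher (1.30, SE 0.29), while Nnat (-0.45, SE 0.11) and Neurog3 (-0.31, SE 0.08) were lower. Neurog3 lost its call without C3H replicate 3 or NZO replicate 3 or 4 (limma adjusted p up to 0.0552). Adjusted over the list alone, 6 were higher and 2 lower. Camera of limma called the list, whose median was 0.36 (adjusted p = 0.00641), but not with an estimated correlation (adjusted p = 0.391). The call of this list also ended above median brightness and without NZO replicates 4 and 5. Aldh1a3, an enzyme of retinoic acid synthesis, kept its value (1.63) with the acinar score as a covariate, whereas the medians of the disallowed (-0.23) and stress (-0.28) lists turned negative.

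Of 22 genes of oxidative phosphorylation and the citric acid cycle, only fumarate hydratase Fh1 passed, over all genes and adjusted over the list alone, and it was 2.58-fold lower in NZO (-1.37, SE 0.09). The list, with a median of -0.10, was called lower by camera of limma (adjusted p = 0.00641, adjusted p = 0.391 with an estimated correlation), with a median of 0.03 when the acinar score was a covariate. That call also ended with the covariate and without NZO replicates 4 and 5. The remaining lists were not called by camera of limma. Of 13 lipogenesis genes, the desaturases Scd1 (-0.55, SE 0.11) and Scd2 (-0.89, SE 0.09) and Dgat2 (-0.34, SE 0.09) were lower and Pnpla3 (0.37, SE 0.07) and Me1 (0.42, SE 0.08) higher. Adjusted over the list alone, 4 were lower and 2 higher. The list median was -0.17, with a camera adjusted p of 0.0827 in limma that fell to 0.0439 without C3H replicate 4 and to 0.0260 without NZO replicate 2. Among 15 genes of fatty acid oxidation, Cpt1a (0.50, SE 0.08), the fatty acid transporter Cd36 (1.78, SE 0.31) and Plin2 (0.67, SE 0.18) were higher and Hadh was lower (-0.85, SE 0.17). Adjusted over the list alone 4 were higher and 1 lower, with a list median of 0.02 (camera of limma, adjusted p = 0.244). The values of Cd36 (0.06), Hadh (-0.07) and Plin2 (-0.26) no longer passed with the acinar score as a covariate. Among 12 hypoxia genes, Car9 (1.33, SE 0.27) and Egln3 (1.13, SE 0.22) were higher and Pdk1 was lower, at 9.13 ± 0.18 in C3H and 8.14 ± 0.24 in NZO. The same 3 passed adjusted over the list alone, with a list median of 0.02 (camera of limma, adjusted p = 0.681). The medians of the other lists lay near 0, at -0.08 for 26 genes of endoplasmic reticulum stress, 0.08 for 18 of oxidative stress, 0.05 for 14 of glycolysis, -0.05 for 16 of cholesterol synthesis, 0.04 for 13 immediate early genes and -0.03 for 15 ribosomal protein genes, whose mean was 0.05 and whose camera direction was higher. The corresponding camera adjusted p values of limma were 0.251, 0.287, 0.780, 0.335, 0.309 and 0.495. In the order of these lists 3, 3, 0, 2, 2 and 1 members passed, and 3, 8, 0, 3, 4 and 1 adjusted over the list alone. Among them were Gstm1 (-0.96, SE 0.12), Sdf2l1 (-0.42, SE 0.09), Nsdhl (-0.61, SE 0.07), Dusp1 (0.31, SE 0.08) and Rps3 (0.75, SE 0.08). Single arrays left out ended the calls of Plin2 (C3H replicate 1, 3 or 4, or NZO replicate 3, 4 or 5, limma adjusted p up to 0.0710) and Dusp1 (C3H replicate 1 or 2, or NZO replicate 1, 4 or 5, limma adjusted p up to 0.0978).

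Among 12 measured genes put forward earlier from crosses with NZO mice, Dpp4, which encodes the protease that inactivates incretins, was 2.66-fold higher in NZO (1.41, SE 0.08, limma adjusted p = 4.58e-08), at 9.21 ± 0.07 in C3H and 10.62 ± 0.12 in NZO. The interferon-inducible gene Ifi202b was higher (1.27, SE 0.18), the signalling factor Lefty1 1.97-fold lower (-0.98, SE 0.08) and Pcp4l1 1.34-fold lower (-0.42, SE 0.09). The same 4 genes passed adjusted over the list alone, the list as a whole was not called by camera of limma (median 0.07, adjusted p = 0.244), and Dpp4 (1.41) and Lefty1 (-1.03) also passed with the acinar score as a covariate.

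The second comparison concerned the critical region that the study narrowed down, 30 to 46 Mb, in which it sought genes expressed differently in islets. The chromosome, 7, is known from the study and not from its labels. Within the region the largest differences were the kallikreins Klk1b22, 7.99-fold lower in NZO (-3.00, SE 0.12, limma adjusted p = 2.19e-09), and Klk1b5, 7.29-fold higher (2.87, SE 0.32), which lie in one cluster of near-identical genes. The small heat shock protein gene Hspb6 was 2.04-fold lower (-1.03, SE 0.14), Fxyd3, which encodes a regulator of the sodium pump, 2.01-fold lower (-1.01, SE 0.13), 2200002J24Rik was lower (-0.96, SE 0.08) and the calcium-binding protein gene Rcn3 1.80-fold lower (-0.85, SE 0.13). The short-chain fatty acid receptor Ffar2 was lower (-0.68, SE 0.10), while the peptidase Pepd was 1.41-fold (0.50, SE 0.07), the sulfotransferase Sult2b1 1.43-fold (0.51, SE 0.08) and Pih1d1 1.47-fold higher (0.56, SE 0.09).

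Of 255 genes of the region tested, 32 passed (13 higher and 19 lower in NZO), 35 adjusted over the list alone, and 4 differed by at least 1 log2 unit. That share was not distinguishable from the 10.0% (1978) of the 19683 other genes (two-sided Fisher's exact test, odds ratio 1.28, p = 0.208), nor was the direction of the calls (40.6% higher against 54.4%, Fisher's exact test, p = 0.152). The same window of megabases held a larger share of called genes on chromosome 8 (22.2%) and chromosome 12 (17.2%), and a smaller one on the remaining chromosomes. Gene places come from the assembly GRCm38.p6 and the build behind the study's borders is not given in the sources used here, so the borders are approximate, and with borders of 31 and 45 Mb 10 genes passed. With the acinar score as a covariate 4 genes of the region passed, Klk1b22 (-3.13), Fxyd3 (-1.70), Rcn3 (-1.44) and 2200002J24Rik (-1.13), and with NZO replicates 4 and 5 left out 18 did. Of the other genes named here, Pepd (0.48), Sult2b1 (0.58), Pih1d1 (0.48) and Ffar2 (-0.66) had values near those without the covariate but did not pass, while Hspb6 (-0.68) and Klk1b5 (1.01) had smaller ones.

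**Figure D2:**
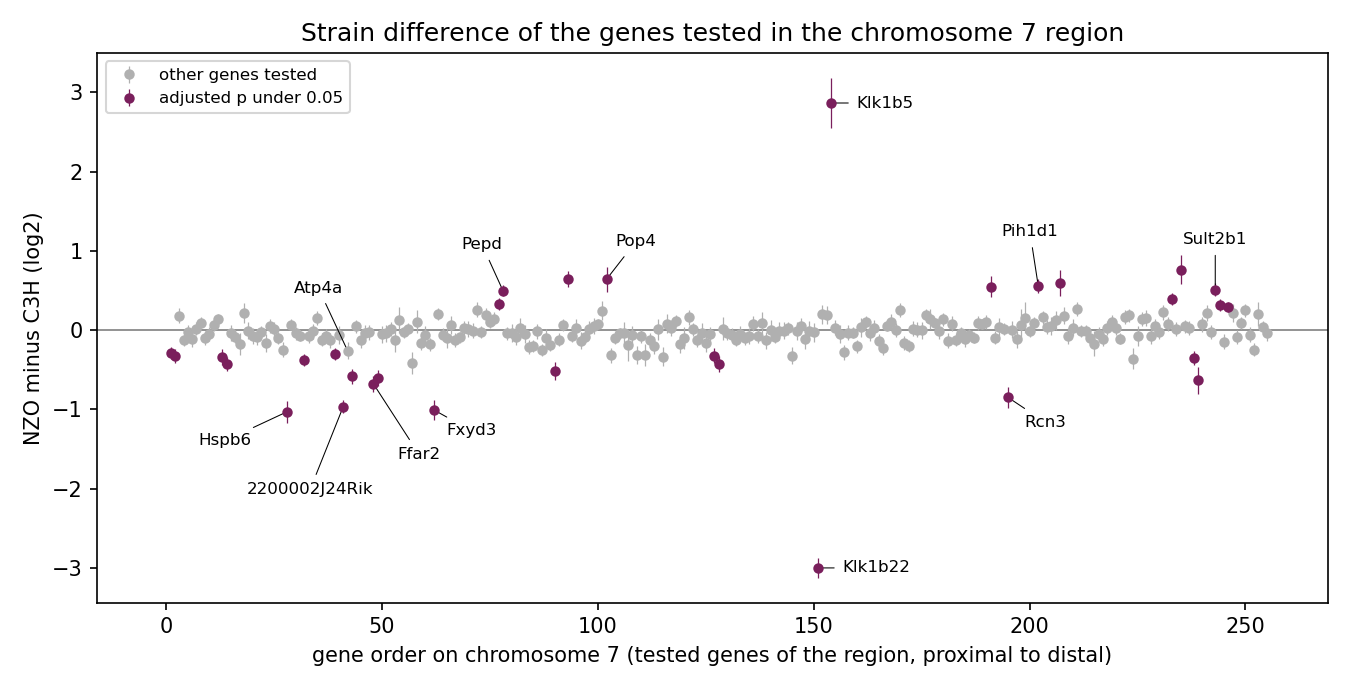
NZO minus C3H difference in log2 units (y axis, with its SE as the bar) of the 255 genes tested in the chromosome 7 region, in their order along the chromosome in GRCm38.p6 (x axis). The 32 genes with a limma adjusted p below 0.05 are dark, Klk1b5 (2.87) and Klk1b22 (-3.00) lie farthest from 0, and the first 12 dark genes from the proximal end lie below 0.

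The third comparison gave the values of Pop4 and Atp4a, which the study is known, though not from its labels, to have put forward in this region. These arrays may have served to choose them, so their results are not taken as independent evidence. The study's other evidence for them is not in the sources used here. Pop4, which encodes a protein subunit of ribonuclease P, was 1.56-fold higher in NZO (0.64, SE 0.16, limma adjusted p = 0.0158), at 8.58 ± 0.21 in C3H and 9.22 ± 0.37 in NZO, and its adjusted p over the region's genes alone was 0.0112 in limma. The strains overlapped, since NZO replicate 2 at 8.73 lay below C3H replicate 2 at 8.82. Atp4a, which encodes the catalytic subunit of the gastric proton pump, was 7.59 ± 0.22 in C3H and 7.33 ± 0.17 in NZO, a difference of -0.26 (SE 0.11) that did not pass (limma adjusted p = 0.186 over all genes and 0.167 over the region alone). Leaving out any 1 array kept the call of Pop4 (limma adjusted p up to 0.0413), but it ended with NZO replicates 4 and 5 left out (0.57, limma adjusted p = 0.0696) and with the acinar score as a covariate (0.38, limma adjusted p near 1). The value of Atp4a was 0.11 with that covariate.

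Abcc8 and Kcnj11, which encode the 2 subunits of the beta cell's ATP-sensitive potassium channel, lie just beyond the distal border. Abcc8 was 10.61 ± 0.17 in C3H and 10.99 ± 0.24 in NZO, a difference of 0.38 (SE 0.12) that missed the threshold (limma adjusted p = 0.0559) and passed without C3H replicate 3 (0.44, limma adjusted p = 0.0439) and without NZO replicate 4 (0.49, limma adjusted p = 0.00501). Abcc8 also passed with NZO replicates 4 and 5 both left out (0.49, limma adjusted p = 0.0139), where Pop4 did not, and was 0.67 with the acinar score as a covariate (limma adjusted p = 0.367). Kcnj11 differed by 0.11 (SE 0.11, limma adjusted p = 0.683).

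**Figure D3:**
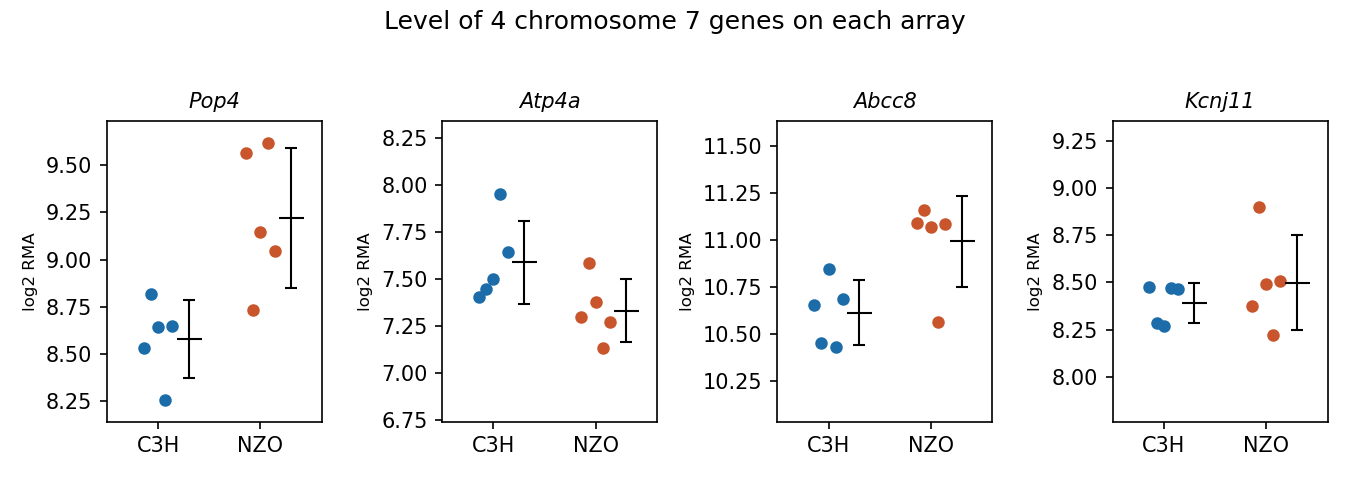
Log2 RMA value (y axes, panels of equal height in log2 units) of Pop4, Atp4a, Abcc8 and Kcnj11 on each of the 5 C3H and 5 NZO arrays (points), with the mean and SD of each strain (black bars). Pop4 averaged 8.58 in C3H and 9.22 in NZO with overlapping arrays, and in Abcc8 NZO replicate 4 (10.56) lay apart from the other NZO arrays (11.07 to 11.16).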

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

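Of the tests in this part, the correlation of acinar genes within strains, the comparison of the Reg genes with lists of acinar genes and the test of a lower share of beta cells were chosen after their result had been seen. Of 302 groups of 5 arrays examined, 15 (4.97%) held an array far from the other 4 by Dixon's criterion, about the 1 in 20 that chance gives, but 8 of the 15 were C3H replicate 4. That array had the highest median of its strain (7.052, others 6.926 to 6.952), a duct mean of 8.448 (others 8.653 to 8.722), a lymphocyte mean of 6.655 (6.118 to 6.272) and an endoplasmic reticulum stress mean of 11.48 (11.56 to 11.59). It was also apart in Nefm (7.939, others 8.707 to 8.892), Fggy (8.544, others 8.926 to 9.065), Ndst4 (6.683, others 7.208 to 7.419) and Scd1 (8.68, others 9.03 to 9.17). NZO replicate 2 was apart in the endothelial mean (8.988, others 9.243 to 9.313) and Gstm1 (9.59, others 8.959 to 9.058), and NZO replicate 4 in Abcc8 (10.56, others 11.07 to 11.16). The remaining 4 values were Plk1 on C3H replicate 2 (6.441, others 6.617 to 6.665), Bub1 on C3H replicate 1 (5.088, others 5.234 to 5.281), Cxcl12 on C3H replicate 3 (6.2, others 6.321 to 6.367) and Car9 on C3H replicate 5 (7.054, others 6.335 to 6.524). Among probe sets outside the gene table, 477 passed the same limma test, 100 of the 1621 that name several genes and 377 of the 12146 that are not named here.

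Chance was an unlikely source of the number of genes that differed. Splits of the arrays cannot tell strain from a preparation difference that went with strain. Of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, gave as many as 2010 genes, and the highest of the others, which exchanged C3H replicate 4 and NZO replicate 1, gave 1528. The 32 region genes were also reached in only 1 of 100 splits (highest other 15). The region count followed the total, since the 15 came from the split with 1528 genes. It therefore says nothing about the region apart from the rest of the genome. Chance cannot be excluded for the number of gene lists past the threshold, 17, since 14 of the 100 splits gave as many and the highest other gave 22. The split with 22 lists called 0 genes. Adjusted p values of camera at the preset correlation therefore cannot be read as error rates of single lists.

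Acinar and Reg transcripts were higher in NZO, and within strains, where strain plays no part, the 24 acinar genes rose and fell together between arrays with a mean residual correlation of 0.764, where the highest of 1000 random lists matched on expression gave 0.417. The same correlation was as high for the stellate (0.804) and macrophage (0.768) lists and was 0.691 for the Reg list, so it was not particular to acinar genes. A varying carry-over of acinar tissue through islet isolation would give such co-variation and is a candidate explanation, but the comparison with random lists cannot single it out. A regulated acinar programme was not tested. With the acinar score as a covariate the mean Reg level was still 0.497 higher in NZO (95% interval 0.0186 to 0.975, against 2.10, 1.37 to 2.83, without it), and an interval above 0 had been set in advance to count against carry-over as the whole cause. That bound was too narrow, because among 1000 lists of 7 acinar genes, tested with a score from the other acinar genes, the middle 95% of the differences lay between -0.485 and 0.519. Carry-over as the whole cause of the Reg difference therefore stays open, as does a strain difference in the acinar transcripts themselves, since all NZO scores lay above all C3H scores.

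Of 19 beta cell identity genes, 6 were lower in NZO, and the list was called lower by camera of limma, but not with an estimated correlation (adjusted p = 0.391). With the acinar score as a covariate the mean difference of the list was 0.0852 (95% interval -0.183 to 0.354), against -0.384 (-0.618 to -0.149) without it, and the SE moved only from 0.102 to 0.114, so the fall of the list mean may go with whatever varied along with the acinar score. A lower share of beta cells in the RNA would lower the members alike only if each were confined to beta cells and measured without compression. Neither condition was tested. The members did not fall by a common amount. Of those below the bright end of the scale, 66.7% (10 of 15) had a 95% interval that excluded their median of -0.449, with Slc2a2 at -2.17 to -0.92 and Nkx6-1 at -0.30 to 0.31. These unequal falls cannot decide whether a lower share, or dilution of beta cell RNA by acinar RNA, was the whole cause. Both stay open, as does a change within the beta cells, by strain or by the state of a preparation that also carried more acinar RNA.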

How the results depend on the processing

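The acinar score as a covariate and the joint omission of NZO replicates 4 and 5 were chosen after the data had been seen. The delta and PP cell list kept its direction and its call under all 21 alternatives (median -0.53 to -0.40), and the Reg list stayed higher under all of its alternatives, as did the acinar list, which was not tested with its own score as a covariate. Both lost their call only with an estimated correlation.

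The 2010 genes became 4125 with array weights (1994 of the 2010 among them), 206 with the acinar covariate (187 shared), 1105 without NZO replicates 4 and 5 (1051 shared) and 232 at a difference of at least 1, a stricter threshold. Leaving out 1 array gave 1441 (C3H replicate 1) to 2701 (C3H replicate 4). The 1090 higher genes became 1815, 113 and 613 with weights, covariate and without the 2 arrays (772 to 1509 with 1 array left out), and the 920 lower genes 2310, 93 and 492 (641 to 1574). The share of higher genes fell from 54.2% to 44.0% with array weights, 47.4% with centring and 41.7% without C3H replicate 4, and rose to 61.0% without NZO replicate 2, so the balance of directions depended on these choices. Of the called genes, the 232 at a difference of at least 1 became 146 with the covariate (204 to 298 with 1 array left out). The 32 region genes became 54 with weights, 4 with the covariate, 18 without the 2 arrays and 10 with borders of 31 and 45 Mb, which holds fewer genes (24 to 42 with 1 array left out). The 17 lists became 11 above median brightness, 7 with the covariate, 1 with an estimated correlation and 12 without the 2 arrays (16 to 18 with 1 array left out). Above median brightness the granule, alpha, duct, cell cycle and beta cell stress lists lost their call. Fry did not call the granule, duct, macrophage, stellate, antigen presentation, inflammation and disallowed lists. Of the 7 with the covariate, only the delta and PP, interferon and Reg lists kept their direction and call. The macrophage, stellate and disallowed lists were called in the opposite direction, and stimulus coupling was called only there. The 5 lists that lost their call without the 2 arrays were granule (median -0.06), stellate (0.11), inflammation (0.06), oxidative phosphorylation (-0.07) and beta cell stress (0.16). The candidates past the threshold, 1 (Pop4), became 2 with Abcc8 under both brightness filters, where fewer genes are tested, and with a second quantile normalization, trend and robust settings, and array weights, and 0 with the covariate (1 to 2 with 1 array left out). Without the 2 arrays the count was also 1, but the gene was Abcc8 and not Pop4. Except where construction gives it, the cause was not tested.

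With the acinar covariate the medians of 16 of the lists changed sign. They became 0.086 (beta cell identity), 0.085 (granule), 0.15 (stimulus coupling), -0.20 (duct), -0.49 (macrophage), -0.45 (stellate), -0.065 (antigen presentation), -0.21 (inflammation), -0.23 (disallowed), -0.28 (beta cell stress), -0.01 (cell cycle) and 0.03 (oxidative phosphorylation), and, in lists not called either way, 0.12 (lipogenesis), -0.06 (oxidative stress), -0.10 (fatty acid oxidation) and -0.19 (immediate early). So did 22 named genes, Atp4a (0.11), which was not called either way, and the called genes Spink1 (-0.53), Dmbt1 (-0.031), Try10 (-0.15), Sytl4 (0.077), Muc1 (-0.22), Onecut2 (-0.023), Fcer1g (-0.051), Csf1r (-0.22), Itgam (-0.41), C1qa (-0.28), Pdgfra (-0.077), Fn1 (-0.57), Cd74 (-0.25), Ptgs2 (-0.21), Lcn2 (-0.34), Tgm2 (-0.15), Cxcl12 (-0.0097), Cck (-0.41), Plin2 (-0.26), Car9 (-0.081) and Fosl1 (-0.082). The cause was not tested for the genes. Of 120 named genes, 29 kept direction and side of the threshold with this covariate, and 87 without the 2 arrays. Without the 2 arrays 32 lost their call, among them Ptgs2, B2m, Pcx, Gipr, Slc7a2 and Sdf2l1. Centring, array weights, a second quantile normalization and the mean of probe sets changed at most 2 of the named genes each. The signal over background of an array limits dim genes, whose differences RMA compresses.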

Other observations

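The permutation test of the order of directions within the region was chosen after the region had been seen, and the genes of the next sentences were chosen after their values were seen. Some genes outside the naming rule differed strongly also with the acinar score as a covariate. Pigr, which encodes the receptor that carries antibodies across epithelia, was 2.63 higher in NZO (3.10 with the covariate), the calcium sensor gene Kcnip3 2.45 (2.93), the deiodinase Dio1 1.77 (2.01), the chemokine Ccl28 1.55 (1.54), the arginine deiminase Padi2 1.40 (1.98), the fatty acid elongase Elovl2 1.38 (1.72), the bile acid receptor Nr1h4 1.36 (1.63) and the nuclear receptor Pparg 0.94 (1.23), each past the threshold of limma in both fits.

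The interferon mean was 0.23 higher in NZO and 0.45 higher with the acinar score as a covariate (95% interval 0.249 to 0.649). Mx1, the member with the largest difference (1.59, and 3.33 with the covariate), weighs on both means. The list median without the covariate was 0.16. The difference of the delta and PP cell mean was -0.62 without and -0.55 with the covariate (-0.853 to -0.255). That of the alpha cell mean was -0.25 and -0.21 (-0.379 to -0.0472). The alpha cell list nevertheless lost its camera call with the covariate, where its median was -0.11, Slc7a2 was -0.01, and Ttr went from 0.01 to -0.69 without passing.

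Sequence differences between the strains can weaken the binding of single probes and so imitate expression differences. Among 53 called genes with another bright probe set of their own, the other probe set moved the same way in 51, or 96.2% (95% interval 87.0 to 99.5). This argues against variants under single probe sets as the whole cause of the differences of these genes as a set. In Fggy, however, the other probe set differed by only -0.38 against -2.08. Apart from Fggy, the largest difference among the 53 was 0.91 (Pdlim1), so differences of at least 1 log2 unit were hardly covered. None of the 53 genes lies in the chromosome 7 region. Probe variants therefore stay open for the larger differences, for that region and for any single gene without a second probe set. Neighbouring called genes less than 1 Mb apart were paired, and pairs whose symbols begin with the same letters were left out. They shared their direction in 55.9% of 1201 pairs, where 10000 permutations of the directions within chromosomes gave a median of 50.4% and at most 55.4% (p = 1e-04, the smallest they can give). A candidate explanation is that neighbours share strain haplotypes or regulatory sequence. Paralogs with unlike symbols and probe sets that share sequence would add to such pairs and were not removed. In the chromosome 7 region, ordered by GRCm38.p6, the first 12 called genes, Zfp14, Zfp82, Clip3, Alkbh6, Hspb6, Igflr1, Haus5, 2200002J24Rik, Tmem147, Ffar2, Ffar3 and Fxyd3, were all lower in NZO. Permutation of the directions of the 32 called genes gave a run as long with p = 0.0029 (10000 permutations, median longest run 5). Among all 62 tested genes that this run of 12 spans, the 12 included, 47 were lower and 15 higher. With the acinar score as a covariate only 2200002J24Rik (-1.13) and Fxyd3 (-1.70) of the 12 passed, and Ffar3 (-0.60 to -0.19), Alkbh6 (-0.43 to -0.15), Clip3 (-0.34 to -0.15), Zfp14 (-0.29 to -0.15) and Zfp82 (-0.32 to -0.17) came nearer to 0, so part of the run may go with the acinar transcripts. Igflr1 (-0.37 to -0.35), Tmem147 (-0.58 to -0.56) and Ffar2 (-0.68 to -0.66) kept about their size and no longer passed at the larger SE. A shared local influence on the 12 genes is a hypothesis these data prompted and cannot test independently.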
